A study of Mus musculus with 7 samples.

How the data were processed

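Total RNA from resting and activated primary mouse CD4 T cells had been hybridized to Affymetrix Mouse Exon 1.0 ST arrays. The deposited table held log2 signals, 1 column for each of 7 arrays, with 2 decimals; the authors made them with Affymetrix Power Tools and RMA per the labels, with versions and options not given in the sources used here. The table has 1 probe set per RefSeq transcript accession, and where that grouping of probes came from is not stated, nor is the genome build, so no coordinates are given. The labels describe the values as gene level. Value columns that belong to no sample numbered 0.

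Symbols were taken from a table pairing RefSeq accessions with genes. Of 43029 probe sets, 17897 got 1 symbol and 25132 none; of the latter most are predicted transcripts, since 16 of 24124 predicted accessions but 17881 of 18905 curated ones got a symbol. For 740 genes with more than 1 probe set, the probe set with the highest mean was used in counts and lists. Over the 7 arrays, 9437 probe sets had the same values as an earlier one. Arrays have no read depth; as a guide to background, 1113 probe sets of olfactory and vomeronasal receptors, which T cells are not known to express, had a 95th percentile of 5.97. The number of arrays limits the precision.

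Groups follow the labels: resting, 6 h and 48 h with 2 arrays each. The third 48 h array was left out of the fit because the labels keep it for another analysis, which was not carried out here, and was only set beside the results. All 6 arrays entered 1 limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with group as the only term and 3 contrasts. Residual degrees of freedom were 3, prior degrees of freedom 1.25 and the median posterior SD 0.116. Rounding to 2 decimals gives some probe sets a residual variance of 0, which limma reports as offset. All 43029 probe sets were tested, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05; the choice had been written for transcript clusters, and the probe set is the unit the table holds. Replicate numbers are not stated to pair samples, so the fit has no block.

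The 28 gene lists, the test of each result, the rule for named genes and most alternatives were fixed before the data were examined. The lists cover activation, growth, metabolism, cell division, RNA processing, survival, interferon response and markers of other cell types. Each list was tested with camera (preset correlation 0.01), adjusted over 84 tests of 28 lists in 3 contrasts, and again with the correlation estimated and with fry, which asks whether a list moves on balance (55 called of 84) or in either direction (84 of 84) and does not compare it with other genes. With the preset correlation 58 of 84 were called, and 0 with an estimated correlation, where the lowest adjusted p was 0.360. The estimated version called no list even where nearly all members rose, such as replication at 48 h (46 of 47). Named genes are, per comparison, the 6 largest rises and 6 largest falls that passed with no overlap between groups, up to 4 passing members per list (up to 2 as values where none passed), and a fixed set: Cd69, Cd4, Il2, Il2ra, Ifng, Myc, Cstf2, Cpsf6, Nudt21 and the depletion targets, of which Cd8a and Ly6g had no named probe set.

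The pipeline was tested on simulated data with the arrays' own noise. At an absolute log2 change of 0.5, 1, 2 and 4, it recovered 0%, 42%, 88% and 96% of changed genes at 6 h, with 2%, 48%, 90% and 96% at 48 h and 0%, 66%, 86% and 96% for 48 h against 6 h. Expectations for the shared resting arrays and for the third 48 h array came from 20 simulated tables.

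Alternatives were leaving out each array, adding the third 48 h array, a replicate block, quantile, 75th percentile and cyclic loess scaling, filters on dim or unnamed probe sets, another variance model, fitting only the compared groups, and stricter thresholds. Further alternatives, chosen after seeing the data, were dropping identical probe sets, testing 1 probe set per gene, a background filter, and leaving out genes at least 0.5 higher on resting 1 than on resting 2. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.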

Results

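Primary mouse CD4 T cells, prepared from spleen and lymph nodes by magnetic depletion of other lineages, were profiled on 7 exon arrays at rest and after stimulation with beads carrying antibodies to CD3 and CD28. There were 2 arrays of resting cells, 2 at 6 h and 2 at 48 h, described by the labels as biological replicates. The labels reserve the third 48 h array for another analysis. The table gave a log2 signal for 43029 probe sets, of which 17897 carried 1 gene symbol and covered 16914 genes. Array medians lay between 6.0 and 6.2, and the number of arrays limits the precision. Errors are the SD of 2 arrays (n = 2) for levels and the limma standard error (SE) for log2 changes. Gene counts use 1 probe set per gene and a Benjamini-Hochberg adjusted p threshold of 0.05.

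The first comparison, 6 h against rest, addresses the early response to stimulation. The largest rises were in Irf4, a transcription factor induced by antigen receptor signals, from 7.18 ± 0.21 to 12.43 ± 0.035 (log2, mean ± SD, n = 2), and in Il2, the T cell growth factor, from 4.20 ± 0.028 to 9.05 ± 0.30. These were log2 changes of 5.25 (SE 0.16, limma adjusted p = 0.00379) and 4.85 (SE 0.34, adjusted p = 0.00544). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 4.53 (SE 0.52). The cytokine gene Lif rose by 4.31 (SE 0.27) on 1 of its 2 probe sets and 3.50 on the other, the kinase gene Plk2 by 4.28 (SE 0.45) and Spry1, a feedback inhibitor of growth factor signalling, by 4.24 (SE 0.10). The largest falls were in Jchain at -3.85 (SE 0.64), which encodes the joining chain of secreted antibodies, Dapl1 at -3.56 (SE 0.13), Igfbp4 at -3.51 (SE 0.29), BC147527 at -3.48 (SE 0.31), Sema4a at -3.46 (SE 0.20) and Pglyrp2 at -3.42 (SE 0.20). Cd69, whose protein was stained at 6 h to monitor activation, rose by 2.06 (SE 0.084), and Cd4 fell by 0.98 (SE 0.060) from a resting level of 11.76 ± 0.057 (SD, n = 2).

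Lists of early activation genes were higher at 6 h by camera, the list test in limma, with adjusted p = 0.360 or higher with an estimated correlation. Of 34 immediate early and activation transcription factors, 19 rose and 0 fell, and 22 passed adjusted over the list alone. Nr4a3 rose by 3.48 and Nr4a2 by 3.21, both nuclear receptors induced by antigen receptor signals, and Myc rose by 1.41. The list test gave adjusted p = 2.0e-08, and adjusted p = 0.360 with an estimated correlation. Among 24 activation and costimulatory receptors, 14 rose and 0 fell, with 15 adjusted over the list alone, led by Tnfrsf9 at 3.24, Il2ra at 2.78, which encodes the alpha chain of the interleukin 2 receptor, Cd200 at 2.57 and Tfrc at 2.27 (list adjusted p = 1.6e-07, and adjusted p = 0.360 with an estimated correlation). Among 29 cytokines and chemokines, 8 rose and 1 fell, with 12 adjusted over the list alone. Ccl3 rose by 3.56 and Cxcl10 by 2.13, while Ifng had a change of 1.30 that did not pass (limma adjusted p = 0.0594). That list had adjusted p = 0.00387, and adjusted p = 0.413 with an estimated correlation. Of 28 feedback regulators of signalling, 13 rose, such as Dusp4 at 2.92 and Rgs16 at 2.61, and 3 fell, such as Socs3 at -2.21, with 21 adjusted over the list alone (list adjusted p = 1.4e-04, and adjusted p = 0.360 with an estimated correlation). Of 25 BCL2 family and p53 target genes, 10 rose, among them Gadd45b at 3.60, Bcl2l1 at 2.96 and Bax at 1.94, and 4 fell, with 17 adjusted over the list alone (list adjusted p = 0.00130, and adjusted p = 0.400 with an estimated correlation).

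Lists of genes for building cell mass, all but the ribosomal proteins, were higher at 6 h by camera, with adjusted p = 0.360 or higher with an estimated correlation. In ribosome biogenesis 41 of 43 members rose and 0 fell, with 43 adjusted over the list alone. Among them were Mrto4 at 2.41, Polr1b at 2.09 and Nop16 at 2.01 (list adjusted p = 5.0e-21, and adjusted p = 0.360 with an estimated correlation). The 30 cytosolic ribosomal proteins were not called as a group, with 3 rising, 4 falling and 11 passing adjusted over the list alone. Rpsa rose by 1.30 and Rps21 fell by 0.64, and the list had adjusted p = 0.0849, and adjusted p = 0.657 with an estimated correlation. In cholesterol synthesis and uptake 14 of 22 rose and 0 fell, with 18 adjusted over the list alone. Among them were Cyp51 at 2.28 and Hmgcs1 at 1.83 (list adjusted p = 3.9e-08, and adjusted p = 0.360 with an estimated correlation). For single-carbon, serine and purine synthesis, 18 of 22 rose and 0 fell, with 20 adjusted over the list alone (list adjusted p = 1.7e-11, and adjusted p = 0.360 with an estimated correlation). Shmt1 rose by 2.81, and Cad, a pyrimidine synthesis gene that this list also holds, by 1.86. Amino acid transporters and tRNA synthetases gave 23 rises and 0 falls among 28, with 23 adjusted over the list alone. The transporter gene Slc7a5 rose by 1.95 and Slc7a1 by 1.91 (list adjusted p = 1.1e-11, and adjusted p = 0.360 with an estimated correlation). Of 37 proteasome subunits, 28 rose, such as Psmd1 at 1.40, and 1 fell, with 36 adjusted over the list alone (list adjusted p = 1.3e-12, and adjusted p = 0.360 with an estimated correlation). Of 32 chaperones and unfolded protein response genes, 22 rose, such as the mitochondrial chaperones Hspa9 at 1.56 and Hspd1 at 1.55, and 1 fell, with 26 adjusted over the list alone (list adjusted p = 1.1e-10, and adjusted p = 0.360 with an estimated correlation). Glycolysis and glucose or lactate transport had 6 rises and 1 fall among 18, with 12 adjusted over the list alone; Hk2, which phosphorylates glucose, rose by 2.98 while its relative Hk1 fell by 0.94 (list adjusted p = 0.0482, and adjusted p = 0.720 with an estimated correlation). Of 60 oxidative phosphorylation subunits, 9 rose, including Cycs at 1.33, and 0 fell, with 8 adjusted over the list alone (list adjusted p = 0.00290, and adjusted p = 0.609 with an estimated correlation). Fry, which tests a list without comparing it with other genes, called neither glycolysis (adjusted p = 0.133) nor oxidative phosphorylation (adjusted p = 0.113) at 6 h.

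RNA processing genes were tested as 3 lists at 6 h. Among 24 cleavage and polyadenylation factors, 7 rose and 1 fell, with 11 adjusted over the list alone. Cstf2 rose by 0.48 (SE 0.052), while Cpsf6 at 0.04 and Nudt21 at 0.42 did not pass, with limma adjusted p = 0.868 and adjusted p = 0.434. The list had adjusted p = 8.3e-04, and adjusted p = 0.360 with an estimated correlation. Of 39 splicing regulators, 13 rose, such as Syncrip at 1.05, and 2 fell, Celf2 at -1.56 and Mbnl2 at -1.11, with 26 adjusted over the list alone (list adjusted p = 7.1e-05, and adjusted p = 0.360 with an estimated correlation). Of 19 microRNA pathway proteins, 2 rose, Xpo5 at 0.81 and Dgcr8 at 0.51, and 3 fell, among them Mov10 at -1.04, with 8 adjusted over the list alone. That microRNA list had adjusted p = 0.855, adjusted p = 0.893 with an estimated correlation, a median of 0.045 and a mean of -0.014.

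Naive, T cell receptor and interferon lists were lower at 6 h by camera, with adjusted p = 0.360 or higher with an estimated correlation. Of 39 naive and quiescence genes, 23 fell and 2 rose, with 34 adjusted over the list alone; besides Dapl1 and Igfbp4, Tsc22d3 fell by 2.65 and Pik3ip1, an inhibitor of PI3 kinase, by 2.29 (list adjusted p = 1.6e-09, and adjusted p = 0.360 with an estimated correlation). Of 28 T cell receptor complex and proximal signalling genes, 13 fell, such as Txk at -2.05 and Themis at -1.82, and 2 rose, with 18 adjusted over the list alone (list adjusted p = 0.00134, and adjusted p = 0.400 with an estimated correlation). Among 31 interferon-stimulated genes, 16 fell and 0 rose, with 19 adjusted over the list alone. Among them were Usp18 at -2.29 and Ddx58 at -2.28 (list adjusted p = 1.0e-07, and adjusted p = 0.360 with an estimated correlation). Cell division lists were lower by camera, with adjusted p = 4.6e-05 for replication and adjusted p = 5.1e-09 for mitosis, against adjusted p = 0.575 and adjusted p = 0.485 with an estimated correlation. Fry called neither list, with adjusted p = 0.116 and adjusted p = 0.0775. Among the genes, 10 of 47 DNA replication and nucleotide synthesis genes fell and 1 rose, with 14 adjusted over the list alone, and 8 of 52 mitosis and cytokinesis genes fell and 0 rose, with 5 adjusted over the list alone. Rrm2 fell by 1.68 (SE 0.32), Ccne1 by 1.35 (SE 0.21) and Kif23 by 1.31 (SE 0.090). Median levels of these lists differed between the resting arrays, at 0.24 for replication and 0.41 for mitosis on resting 1 and -0.24 and -0.41 on resting 2, relative to their mean. Of 12 cytotoxic granule genes, Srgn rose by 0.97 and Gzmm by 0.70 and Prf1 fell by 1.87, with 4 adjusted over the list alone. Their list median was 0.08, its mean -0.16, with adjusted p = 0.891, and adjusted p = 0.964 with an estimated correlation.

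Some markers of other cell types fell beside the genes of the resting state at 6 h. Of 16 B cell markers 5 fell, such as Cd79b at -1.09, and 1 rose, with 7 adjusted over the list alone. Cd19, whose protein was a depletion target, had -0.08 and did not pass (adjusted p = 0.645). The B cell list had adjusted p = 5.4e-04, and adjusted p = 0.360 with an estimated correlation. Of 26 myeloid and dendritic cell markers 5 fell and 0 rose, with 10 adjusted over the list alone. Among them was Itgam, which encodes the depletion target CD11b, at -1.14 (list adjusted p = 2.2e-05, and adjusted p = 0.360 with an estimated correlation). Of 14 CD8, NK and gamma-delta T cell markers 3 fell and 0 rose, with 4 adjusted over the list alone. Among them were Klrd1 at -1.88 and Itga2 at -0.44, which encodes the depletion target CD49b (list adjusted p = 6.5e-04, and adjusted p = 0.360 with an estimated correlation). Of 13 erythroid markers 0 rose and 0 fell by limma, with 5 adjusted over the list alone. Car1, a carbonic anhydrase abundant in red cells, had a change of -2.34 (adjusted p = 0.0706), and the list had adjusted p = 0.0795, and adjusted p = 0.580 with an estimated correlation. Of 19 stromal and endothelial markers 2 fell, Vim at -2.50, which encodes the intermediate filament vimentin, and Pecam1 at -1.56, with 2 adjusted over the list alone (list adjusted p = 0.291, and adjusted p = 0.609 with an estimated correlation).

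At 6 h, 3525 genes (20.8% of 16914) passed, of which 1823 rose and 1702 fell, and of these 628 rose and 689 fell by at least 2-fold. The balance turned with cyclic loess scaling, to 1724 rises and 1935 falls, and at adjusted p under 0.01, to 485 and 583. Falls also outnumbered rises when either resting array or 6 h replicate 2 was left out. Limma called 593 genes without 6 h replicate 2, 1198 without resting replicate 1, 1066 without resting replicate 2 and 1195 with the third 48 h array added. Without 6 h replicate 1 it called 0 genes, with 4413 at an unadjusted p under 0.05, and every gene called with all arrays kept its sign in each of these fits.

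**Figure D1:**
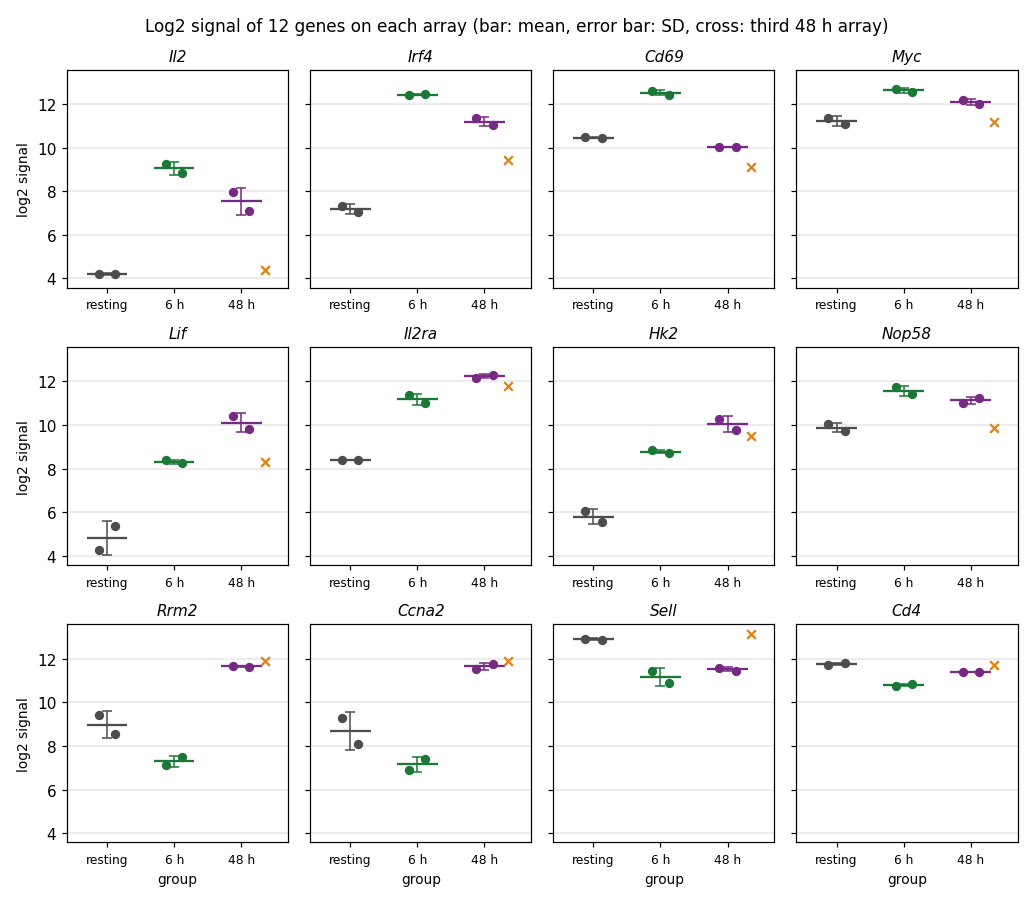
Log2 signal of 12 genes, for each array (points) with the group mean (bar) and SD (error bar, n = 2) at rest, 6 h and 48 h; the cross is the third 48 h array, which is in no mean. Nop58 and Sell lie outside the rule for named genes. Irf4 went from 7.18 at rest to 12.43 at 6 h, and Il2 on the third 48 h array was 4.38 against a 48 h mean of 7.54.

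The second comparison, 48 h against rest, addresses the state of the cells in the later, proliferative phase. The largest rise was in Lif, from 4.20 ± 0.27 to 10.43 ± 0.45 (log2, mean ± SD, n = 2), a change of 6.23 (SE 0.27, limma adjusted p = 0.00321) on 1 probe set and 5.29 on the other. Next came Hk2 at 4.23 (SE 0.24), Irf4 at 4.01 (SE 0.16), Cdkn1a at 3.96 (SE 0.52), the amino acid transaminase gene Bcat1 at 3.94 (SE 0.27) and Il2ra at 3.83 (SE 0.14). The largest fall was in Car1, from 12.60 ± 0.54 to 4.86 ± 0.78 (SD, n = 2), a change of -7.74 (SE 0.58, adjusted p = 0.00547), followed by its relative Car2 at -5.52 (SE 0.49), the interferon-inducible Ifi209 at -5.43 (SE 0.66) and Ifi214 at -4.96 (SE 0.59), Slfn5 at -4.83 (SE 0.13) and Jchain at -4.80 (SE 0.64). Cd69 fell by 0.43 (SE 0.084) and Cd4 by 0.39 (SE 0.060), Myc rose by 0.87 (SE 0.14), and Ifng at -0.19 did not pass (adjusted p = 0.721).

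Cell division genes rose nearly as whole lists at 48 h. Of 47 DNA replication and nucleotide synthesis genes, 46 rose and 0 fell, with 47 adjusted over the list alone. Among them were Ccne2 at 2.97, Rrm2, a subunit of ribonucleotide reductase, at 2.67 and Cdc45 at 2.54 (list adjusted p = 4.5e-19, and adjusted p = 0.360 with an estimated correlation). Of 52 mitosis and cytokinesis genes, 50 rose and 0 fell, with 50 adjusted over the list alone; Bub1, of the spindle checkpoint, rose by 3.45 and Birc5 by 3.27 (list adjusted p = 2.4e-19, and adjusted p = 0.371 with an estimated correlation). Median changes of these lists were 1.75 and 2.73. Metabolic lists were higher as well by camera, with adjusted p = 0.360 or higher with an estimated correlation. In glycolysis 11 of 18 rose and 0 fell, with 14 adjusted over the list alone. Among them were the lactate transporter gene Slc16a3 at 3.58 and Tpi1 at 2.84 (list adjusted p = 1.7e-06, and adjusted p = 0.400 with an estimated correlation). Of 60 oxidative phosphorylation subunits 30 rose, such as Ndufb6 at 1.10, and 1 fell, with 42 adjusted over the list alone (list adjusted p = 8.5e-10, and adjusted p = 0.400 with an estimated correlation). In cholesterol synthesis 20 of 22 rose and 0 fell, with 22 adjusted over the list alone. Among them were Cyp51 at 2.47 and Lss at 2.32 (list adjusted p = 7.5e-13, and adjusted p = 0.360 with an estimated correlation). For single-carbon, serine and purine synthesis 19 of 22 rose and 0 fell, with 20 adjusted over the list alone. Among them were Shmt1 at 2.78 and Psat1 at 2.54 (list adjusted p = 1.6e-09, and adjusted p = 0.371 with an estimated correlation).

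Lists of RNA processing, protein production and turnover, other than ribosomal and microRNA pathway proteins, were higher at 48 h than at rest by camera, with adjusted p = 0.360 or higher with an estimated correlation. In ribosome biogenesis 28 of 43 rose and 0 fell, with 37 adjusted over the list alone. Among them was Nop2 at 1.45 (list adjusted p = 2.0e-11, and adjusted p = 0.400 with an estimated correlation). Amino acid transporters and tRNA synthetases had 21 rises and 0 falls among 28, with 25 adjusted over the list alone, and Slc7a5 rose by 1.99 (list adjusted p = 4.9e-11, and adjusted p = 0.360 with an estimated correlation). Of 37 proteasome subunits 30 rose and 0 fell, with 32 adjusted over the list alone. Among them was Psmd1 at 1.30 (list adjusted p = 1.5e-11, and adjusted p = 0.360 with an estimated correlation). Of 32 chaperones and unfolded protein response genes 25 rose and 2 fell, with 31 adjusted over the list alone; Xbp1, a transcription factor of that response, rose by 1.65 and Dnajb9 fell by 1.94 (list adjusted p = 2.6e-09, and adjusted p = 0.371 with an estimated correlation). Of 39 splicing regulators 17 rose, such as Hnrnpll at 1.10, and 1 fell, with 24 adjusted over the list alone (list adjusted p = 8.1e-05, and adjusted p = 0.360 with an estimated correlation). Of 24 cleavage and polyadenylation factors 4 rose, including Pabpc4 at 1.54 and Cstf2 at 0.68, and 2 fell, including Papolg at -0.74, with 10 adjusted over the list alone (list adjusted p = 0.0336, and adjusted p = 0.408 with an estimated correlation). Cpsf6 at 0.26 and Nudt21 at 0.79 did not pass, with adjusted p = 0.144 and adjusted p = 0.124. Ribosomal proteins had 3 rises and 2 falls among 30, with 5 adjusted over the list alone (list adjusted p = 0.308, and adjusted p = 0.813 with an estimated correlation); their median was -0.048 and, with each array's 75th percentile subtracted, 0.073. MicroRNA pathway proteins had 3 rises and 4 falls among 19, such as Tnrc6b at -1.27, with 8 adjusted over the list alone (list adjusted p = 0.379, and adjusted p = 0.527 with an estimated correlation).

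Activation genes were mixed at 48 h. Of 24 activation receptors 13 rose, with Tfrc at 3.12 and Tnfrsf4 at 2.42, and 2 fell, with 16 adjusted over the list alone (list adjusted p = 5.4e-04, and adjusted p = 0.413 with an estimated correlation). Of 29 cytokines 6 rose, with Il2 at 3.34 and Ccl3 at 3.11, and 1 fell, Ccl5 at -3.14, with 7 adjusted over the list alone (list adjusted p = 0.0376, and adjusted p = 0.544 with an estimated correlation). The immediate early list had 5 rises, such as Bhlhe40 at 3.23, and 3 falls, such as the repressor gene Bcl6 at -2.76, among 34, with 8 adjusted over the list alone (list adjusted p = 0.246, and adjusted p = 0.736 with an estimated correlation). Of 28 feedback regulators 5 rose, with Socs2 at 3.46 and Cish at 2.45, and 12 fell, such as Rgs2 at -2.10, with 21 adjusted over the list alone (list adjusted p = 0.0795, and adjusted p = 0.400 with an estimated correlation). BCL2 family and p53 target genes had 7 rises, such as Bcl2l1 at 2.37, and 5 falls, such as Sesn1 at -1.65, among 25, with 18 adjusted over the list alone (list adjusted p = 0.423, and adjusted p = 0.819 with an estimated correlation). Cytotoxic granule genes had 1 rise, Serpinb6b at 1.60, and 2 falls, Nkg7 at -2.83 and Prf1 at -1.90, among 12, with 3 adjusted over the list alone. Their median was 0.04 and the mean -0.22, with adjusted p = 0.650, and adjusted p = 0.834 with an estimated correlation.

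The lists of naive, T cell receptor and interferon genes were below rest at 48 h by camera, with adjusted p = 0.360 with an estimated correlation. Of 39 naive and quiescence genes 33 fell and 0 rose, with 37 adjusted over the list alone; S1pr1, the receptor for exit from lymph nodes, fell by 4.21 and Txnip by 3.04 (list adjusted p = 4.3e-18, and adjusted p = 0.360 with an estimated correlation). Of 28 T cell receptor and proximal signalling genes 16 fell, with Txk at -2.64 and Card11 at -1.39, and 0 rose, with 20 adjusted over the list alone (list adjusted p = 5.0e-08, and adjusted p = 0.360 with an estimated correlation). Of 31 interferon-stimulated genes 20 fell, with Rtp4 at -4.48 and the transcription factor gene Irf7 at -4.04, and 0 rose, with 23 adjusted over the list alone (list adjusted p = 3.7e-11, and adjusted p = 0.360 with an estimated correlation). Some markers of other blood cells fell beside them. B cell markers fell in 9 of 16 and rose in 0, with 13 adjusted over the list alone. Among them were Cd72 at -2.24 and Cd19 at -0.53 (list adjusted p = 1.4e-06, and adjusted p = 0.360 with an estimated correlation). Myeloid and dendritic markers fell in 13 of 26 and rose in 0, with 15 adjusted over the list alone. Among them were the class II gene H2-Aa at -3.82 and the lysozyme gene Lyz2 at -3.52 (list adjusted p = 1.7e-06, and adjusted p = 0.360 with an estimated correlation). CD8, NK and gamma-delta markers fell in 5 of 14 and rose in 0, with 6 adjusted over the list alone. Among them was Klrd1 at -4.64 (list adjusted p = 8.0e-04, and adjusted p = 0.360 with an estimated correlation). Erythroid markers fell in 6 of 13 and rose in 0, with 6 adjusted over the list alone. Among them were Ermap at -2.86 and Rhd at -2.49 (list adjusted p = 0.00374, and adjusted p = 0.400 with an estimated correlation). The erythroid list had a median of 0.31 on resting 1 and -0.31 on resting 2 relative to their mean, against -0.37 and -0.43 on the 48 h arrays. Stromal markers had 2 rises, Vim at 0.37 and Col1a1 at 0.28, and 1 fall, Pecam1 at -2.07, among 19, with 3 adjusted over the list alone, a median of 0 and a mean of -0.086 (list adjusted p = 0.855, and adjusted p = 0.938 with an estimated correlation).

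**Figure D2:**
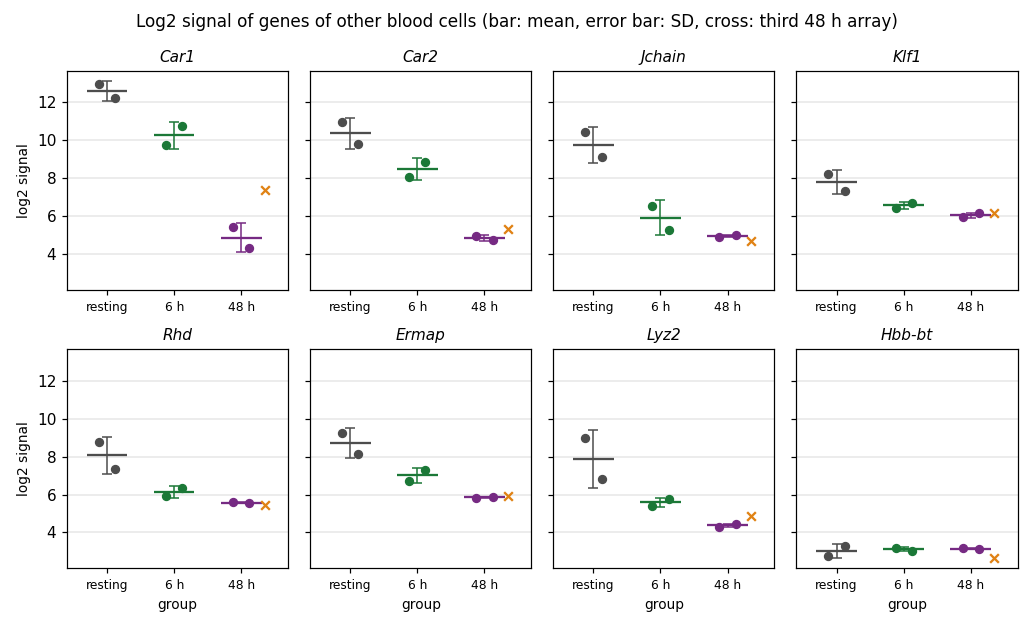
Log2 signal of 8 genes of other blood cells, for each array (points) with the group mean (bar) and SD (error bar, n = 2); the cross is the third 48 h array. Klf1 and Hbb-bt lie outside the rule for named genes. Car1 went from 12.60 at rest to 4.86 at 48 h, and Hbb-bt was at 3.04 at rest.

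At 48 h, 4176 genes (24.7%) passed, of which 2004 rose and 2172 fell, and of these 789 rose and 844 fell by at least 2-fold. With each array's 75th percentile subtracted, which moved the median change of all genes from 0.03 to 0.15, the share rising was 62.2% in place of 48.0%, and rises also outnumbered falls with quantile scaling (2399 and 2078) and cyclic loess (2220 and 2186). The share moved the other way at adjusted p under 0.01, to 38.6% (535 rises and 850 falls). It was also lower when any 1 array other than 48 h replicate 2 was left out. Limma called 2091 genes without resting replicate 1, 1673 without resting replicate 2, 2086 without 6 h replicate 1, 2086 without 6 h replicate 2, 2505 without 48 h replicate 1 and 2058 with the third 48 h array added.

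The third comparison, 48 h against 6 h, addresses what changed between the early and the late state. The largest rise was in the histone gene H2ac4, from 4.05 ± 0.55 to 9.73 ± 0.042 (log2, mean ± SD, n = 2), a change of 5.68 (SE 0.56, limma adjusted p = 0.00998). The 6 h mean lay below the background guide of 5.97, so the size and rank of this change depend on the floor of the array. Next were Pclaf, a partner of the replication clamp, at 5.14 (SE 0.22), Bub1 at 5.03 (SE 0.42), Scd1, a fatty acid desaturase gene, at 4.66 (SE 0.24), and Ccna2 at 4.49 (SE 0.45) and Top2a at 4.48 (SE 0.38), genes of the cell cycle. The largest falls were in Car1 at -5.40 (SE 0.58), Ifi214 at -4.59 (SE 0.59), Ifi209 at -4.11 (SE 0.66), Bcl6 at -3.83 (SE 0.16), Car2 at -3.62 (SE 0.49) and Spry1 at -3.21 (SE 0.10). Il2ra rose further by 1.06 (SE 0.14), Cd4 rose by 0.59 (SE 0.060), Cd69 fell by 2.49 (SE 0.084) and Ifng by 1.49 (SE 0.30), while Il2 at -1.51 and Myc at -0.54 did not pass, with adjusted p = 0.0573 and adjusted p = 0.0784.

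Replication genes rose in 46 of 47 from 6 h to 48 h and fell in 0, with 46 adjusted over the list alone, and mitosis genes rose in 50 of 52 and fell in 0, with 52 adjusted over the list alone. Rrm2 rose by 4.35, Cdc6 by 4.12 and Tpx2 by 4.40; the lists had adjusted p = 3.1e-25 and adjusted p = 2.4e-28, against adjusted p = 0.360 with an estimated correlation for each. Glycolysis rose in 9 of 18 and fell in 0, with 14 adjusted over the list alone. Among them was Aldoc at 2.44 (list adjusted p = 2.0e-06, and adjusted p = 0.400 with an estimated correlation). Oxidative phosphorylation rose in 15 of 60 and fell in 2, with 22 adjusted over the list alone; Ndufv3 rose by 1.14 and Cycs, cytochrome c, fell by 1.83 (list adjusted p = 1.1e-06, and adjusted p = 0.413 with an estimated correlation). Fry did not call oxidative phosphorylation here (adjusted p = 0.0590). Cholesterol synthesis rose in 12 of 22 and fell in 1, with 17 adjusted over the list alone. Among them was Mvd at 1.59 (list adjusted p = 4.8e-05, and adjusted p = 0.400 with an estimated correlation).

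Camera called 9 lists as lower at 48 h than at 6 h, with adjusted p = 0.360 or higher with an estimated correlation, and activation receptors and cytokines were not among them. Immediate early genes fell in 16 of 34 and rose in 0, with 22 adjusted over the list alone. Among them were Nr4a2 at -3.17 and Relb at -2.21 (list adjusted p = 2.9e-06, and adjusted p = 0.360 with an estimated correlation). Feedback regulators fell in 14 of 28, such as Rgs2 at -2.84 and Tnfaip3 at -2.65, and rose in 2, including Socs2 at 3.14, with 21 adjusted over the list alone (list adjusted p = 3.1e-05, and adjusted p = 0.360 with an estimated correlation). Ribosome biogenesis fell in 13 of 43 and rose in 0, with 26 adjusted over the list alone. Among them was Pwp2 at -1.39 (list adjusted p = 5.1e-10, and adjusted p = 0.407 with an estimated correlation). BCL2 family and p53 targets fell in 10 of 25, such as Gadd45b at -2.61, and rose in 2, including Bcl2 at 1.54, with 13 adjusted over the list alone (list adjusted p = 0.00171, and adjusted p = 0.400 with an estimated correlation). Naive genes fell in 15 of 39, such as Klf2 at -1.78, and rose in 2, including Dapl1 at 2.86, with 26 adjusted over the list alone (list adjusted p = 8.0e-05, and adjusted p = 0.360 with an estimated correlation). Interferon-stimulated genes fell in 10 of 31 and rose in 0, with 11 adjusted over the list alone. Among them was Irf7 at -2.23 (list adjusted p = 3.7e-04, and adjusted p = 0.390 with an estimated correlation). B cell markers fell in 6 of 16 and rose in 0, with 6 adjusted over the list alone. Among them was Fcer2a at -1.16 (list adjusted p = 0.00623, and adjusted p = 0.360 with an estimated correlation). Myeloid markers fell in 1 of 26, H2-Aa at -2.86, and rose in 0, with 1 adjusted over the list alone (list adjusted p = 0.0419, and adjusted p = 0.527 with an estimated correlation). Erythroid markers fell in 2 of 13, Car1 and Car2, and rose in 0, with 2 adjusted over the list alone (list adjusted p = 0.0296, and adjusted p = 0.503 with an estimated correlation). Fry called neither the myeloid list (adjusted p = 0.132) nor the erythroid list (adjusted p = 0.0722) between 6 h and 48 h.

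For 14 lists camera made no call between 6 h and 48 h. Activation receptors rose in 4 of 24 and fell in 5, such as Fasl at -2.75, with 13 adjusted over the list alone (list adjusted p = 0.423, and adjusted p = 0.834 with an estimated correlation). Cytokines rose in 3 of 29, such as Lta at 2.25, and fell in 3, with 12 adjusted over the list alone, a median of -0.12 and a mean of 0.015 (list adjusted p = 0.488, and adjusted p = 0.834 with an estimated correlation). T cell receptor genes rose in 3 of 28, such as Themis at 1.81, and fell in 8, such as Zap70 at -1.31, with 18 adjusted over the list alone (list adjusted p = 0.259, and adjusted p = 0.731 with an estimated correlation). Cytotoxic granule genes fell in 2 of 12, Srgn and Gzmm, and rose in 0, with 2 adjusted over the list alone (list adjusted p = 0.483, and adjusted p = 0.766 with an estimated correlation). Ribosomal proteins rose in 2 of 30 and fell in 2, with 3 adjusted over the list alone (list adjusted p = 0.542, and adjusted p = 0.870 with an estimated correlation). Single-carbon, serine and purine synthesis rose in 4 of 22, such as Phgdh at 0.93, and fell in 2, with 7 adjusted over the list alone, a median of -0.028 and a mean of 0.069 (list adjusted p = 0.679, and adjusted p = 0.949 with an estimated correlation). Amino acid transporters and tRNA synthetases rose in 1 of 28, Slc43a3 at 2.15, and fell in 3, with 4 adjusted over the list alone (list adjusted p = 0.891, and adjusted p = 0.967 with an estimated correlation). Proteasome subunits rose in 2 of 37, including the immunoproteasome gene Psmb8 at 1.42, and fell in 1, with 2 adjusted over the list alone, a median of -0.035 and a mean of 0.053 (list adjusted p = 0.820, and adjusted p = 0.967 with an estimated correlation). Chaperones rose in 2 of 32 and fell in 3, such as Dnajb9 at -2.11, with 11 adjusted over the list alone (list adjusted p = 0.893, and adjusted p = 0.967 with an estimated correlation). Polyadenylation factors rose in 2 of 24 and fell in 5, such as Cstf3 at -0.68, with 9 adjusted over the list alone, a median of 0.015 and a mean of -0.058 (list adjusted p = 0.575, and adjusted p = 0.819 with an estimated correlation). MicroRNA pathway proteins rose in 2 of 19 and fell in 3, including Ago1 at -1.25, with 7 adjusted over the list alone (list adjusted p = 0.213, and adjusted p = 0.400 with an estimated correlation). Splicing regulators rose in 4 of 39, such as Celf2 at 1.59, and fell in 2, with 7 adjusted over the list alone, a median of -0.030 and a mean of 0.033 (list adjusted p = 0.923, and adjusted p = 0.967 with an estimated correlation). CD8, NK and gamma-delta markers fell in 1 of 14, Klrd1 at -2.76, and rose in 0, with 1 adjusted over the list alone (list adjusted p = 0.650, and adjusted p = 0.819 with an estimated correlation). Stromal markers rose in 2 of 19, including Vim at 2.87, and fell in 1, with 3 adjusted over the list alone (list adjusted p = 0.282, and adjusted p = 0.606 with an estimated correlation).

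From 6 h to 48 h, 3093 genes (18.3%) passed, of which 1367 rose and 1726 fell, and of these 609 rose and 431 fell by at least 2-fold. That balance turned with cyclic loess scaling, to 1657 rises and 1480 falls, and with 75th percentile scaling, to 1687 and 1564. Limma called 0 genes without 6 h replicate 1, with 4220 at an unadjusted p under 0.05, and 0 without 6 h replicate 2, with 4520 at an unadjusted p under 0.05. It called 1759 without resting replicate 1, 1759 without resting replicate 2, 2028 without 48 h replicate 1 and 1894 with the third 48 h array added.

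Both activated groups were set against the same resting arrays. Of the genes, 910 rose at both times and 1125 fell at both, against 216 and 219 expected for independent calls, while 97 rose at 6 h and fell at 48 h and 95 did the reverse, such as Bcl6 and Rrm2. Across genes, which are not independent replicates, the changes from rest correlated at 0.556, against 0.505 in simulated data with no effect and the same shared resting arrays, and their covariance exceeded the simulated 0.014 by 0.209. The share of genes with the same sign at both times was 66.0%, against 66.7% in the simulated data. These shares are not strictly comparable. The deposited values have 2 decimals, so some changes are exactly 0 and count as a different sign from any rise or fall. Simulated values were not rounded. The 2 resting arrays cannot be split between the comparisons, so part of the excess overlap may come from the shared controls. Of the genes that rose at 6 h, 737 fell from 6 h to 48 h, and 531 of those that fell at 6 h rose from 6 h to 48 h. These overlaps share the 6 h arrays with opposite sign, so noise on those arrays adds to them by an amount not estimated here.

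**Figure D3:**
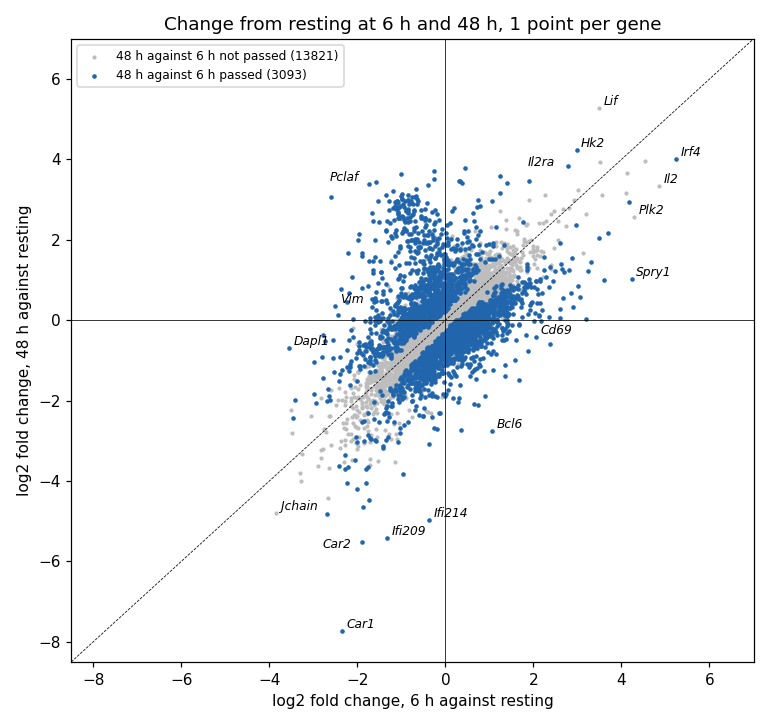
Log2 change from rest at 48 h (vertical axis) against that at 6 h (horizontal axis), 1 point per gene from its probe set with the highest mean; blue points passed in 48 h against 6 h and the dashed line marks equal changes. The 3093 blue points include Pclaf and Vim, above the line, and Bcl6 and Cd69, below it.

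The third 48 h array was set beside the 48 h calls without a test, since it has no replicate. Of 4176 called genes, 3639 (87.1%) differed from the resting mean in the same direction on it, against 54.8% in simulated data where that array did not differ from rest. For changes of at least 2-fold the count was 1533 of 1633 (93.9%). Mitosis genes had a median of 3.06 above the resting mean on that array, against 2.65 and 2.68 on the 48 h replicates, while ribosome biogenesis had -0.27 against 0.87 and 0.71, and naive genes -0.32 against -1.23 and -1.31. Il2 was at 4.38 on it, against 7.54 ± 0.62 (SD, n = 2) at 48 h and 4.20 at rest, and Sell, the lymph node homing receptor gene, was at 13.11 against 11.51 at 48 h and 12.89 at rest; Sell was chosen after its values were seen.

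**Figure D4:**
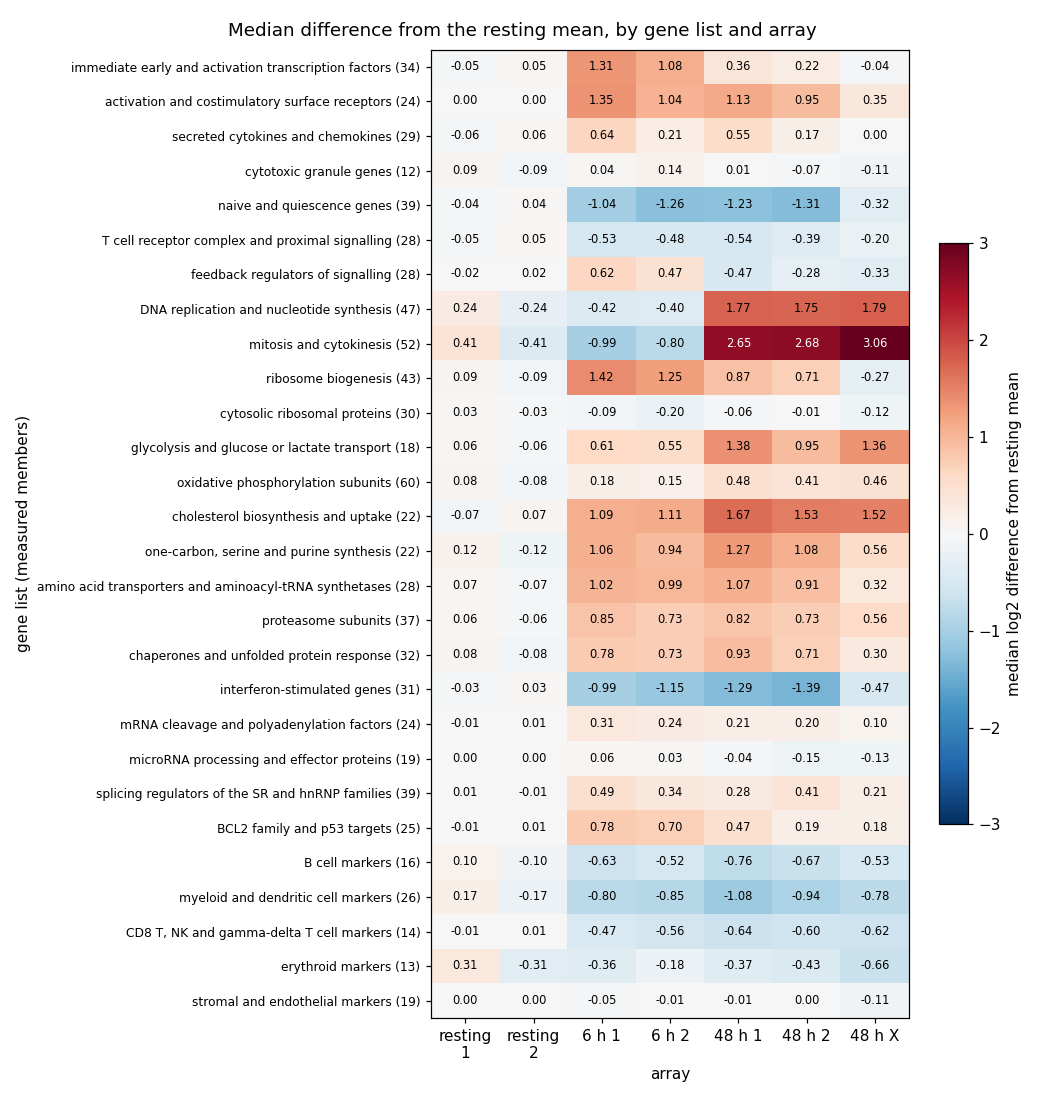
Median log2 difference from the resting mean over the measured members of each of 28 gene lists (vertical axis, members in parentheses) on each of 7 arrays (horizontal axis), as color and number. Mitosis and cytokinesis had -0.99 and -0.80 at 6 h and 2.65 and 2.68 at 48 h, and ribosome biogenesis had 1.42 and 1.25 at 6 h and -0.27 on the third 48 h array.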

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

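All the tests of explanations in this part were chosen only after the result was seen; the gene counts and list calls come from planned tests, except the progenitor counts.

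Genes whose change from rest differed between 6 h and 48 h, tested as 48 h against 6 h in limma, numbered 3093, and 97 rose then fell while 95 fell then rose. As lists, DNA replication and nucleotide synthesis had a median difference of 2.13 and mitosis and cytokinesis 3.54. At 6 h 10 of 47 and 8 of 52 members fell from rest, and the calls of both lists were lost at adjusted p = 0.575 and adjusted p = 0.485 with an estimated correlation. At 48 h 46 and 50 members rose, and the lists had adjusted p = 0.360 and adjusted p = 0.371 with an estimated correlation. Named genes that fell at 6 h and rose by 48 h had differences of 5.14 for Pclaf, 4.35 for Rrm2, 3.66 for Racgap1, 3.58 for Tk1, 3.57 for Ccne1, 3.32 for Ncapd2, 3.25 for Kif23, 2.87 for Vim, 2.65 for E2f2 and 0.96 for Rps20. Those that rose at 6 h and were below rest at 48 h had -3.83 for Bcl6, -2.78 for Trp53inp1, -2.75 for Fasl, -2.65 for Tnfaip3, -2.57 for Bcl2l11, -2.49 for Cd69, -1.83 for Cycs and -1.16 for Fcer2a. The third 48 h array, left out of the main fit, had 56 genes above and 16 below the other 6 arrays by over 1 on the log2 scale. Resting 1 had 100 and 6 and 48 h replicate 1 had 44 and 18. These were counted without the third 48 h array, so against fewer arrays, and such counts are easier to reach.

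The third 48 h array stood apart from the other 48 h arrays, with low ribosome biogenesis and high naive and mitosis genes. Unstimulated cells mixed with activated cells like those of the other 48 h arrays are argued against, since mitosis genes had a median of 0.46 above the 48 h mean (50 of 52 higher). A mix with activated cells that divided more was not tested and could also raise these genes. A compressed scale is argued against, since ribosome biogenesis was below rest (median -0.27, 37 of 43 lower). Oxygen or density of the culture stays open: of 20 oxygen-regulated genes above background whose values had not been seen when their list was made, 15 were higher on that array, with a median of 0.23, short of the 0.3 set for the test, while 17 interferon gamma induced genes not seen before differed more, with a median of 0.815 and 16 higher. Background for the oxygen list was judged with the third 48 h array included, so members could enter only through it, as Stc1 and Vldlr did. This favours higher values on that array. The oxygen list shares 4 of its 30 measured genes with the fixed lists, and 6 had been seen, among them Ccng2 and Tmem45a. The labels give that array no other treatment, so no biological explanation beyond the state of the culture was tested.

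Of 13 erythroid markers limma called 0 at 6 h (5 adjusted over the list alone) and 6 as falling at 48 h (list adjusted p = 0.400 with an estimated correlation), among them the abundant Car1 and Car2, and of 30 genes above background in a second progenitor list 4 fell at 6 h and 10 at 48 h, with no list test. Among all 9970 genes above background at rest, 1653 fell at 6 h and 2097 at 48 h, so at 6 h the second list's share was no higher. Red cells stay open: 8 late red cell genes, all seen before, had a median resting level of 5.62, but 5 of 8 had no group mean above background, and the 3 others, too few to decide, had changes of -0.09, 0.035 and -0.01 at 48 h, none passing, while Gypa, below background, fell by 1.87. This test was reworded after its values were seen: the share above background was undecided, the median below background then spoke against red cells, and a rule that genes near the floor exclude nothing left them open. Blood progenitor cells, which no depletion antibody targets by name, could be a source, but that stays open: over 27 of these 30 genes, whose values had not been seen, the median at 48 h was -0.29, short of the -0.3 set, with 17 lower, although the median on resting 1 was 0.53 above resting 2. Of the 27, 9 passed as falls at 48 h and 21 were higher on resting 1. Including the 3 that had been seen gave medians of -0.51 and 0.44. A first progenitor list, all of whose members had been seen, gave -1.695 and 1.29. In it, 25 of 25 were higher on resting 1 and 10 fell at 48 h. By the median set for this test, a call would thus have needed genes already seen.

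Replication and mitosis genes had medians of -0.38 and -0.90 at 6 h against rest, with 10 of 47 and 8 of 52 falling, adjusted p = 0.575 and adjusted p = 0.485 with an estimated correlation, and no call by fry (adjusted p = 0.116 and adjusted p = 0.0775). The choice of scaling between arrays is argued against, since the mitosis median at 6 h was -0.83 or lower with each of 3 other scalings. Each of these also brings the arrays to a common level, so none could show a change in total RNA per cell. Dividing cells of other types in the resting samples could contribute, since the mitosis median on resting 1 was 0.81 above that on resting 2 (50 of 52 higher), and for replication the gap of 0.48 exceeds the change. Against resting 2 alone the mitosis median at 6 h was -0.56, with 46 of 52 lower, and whether that sample held such cells was not tested. Over the 8 mitosis members that fell, the median gap between the resting arrays was 0.395, though passing limma itself favours a small gap. The gap cannot tell dividing cells of other types from dividing T cells. A change in the T cells themselves stays open and untested.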

How the results depend on the processing

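The tests added after seeing the data were dropping identical probe sets, 1 probe set per gene, a background filter, leaving out genes higher on resting 1, and the alternatives for the third 48 h array. Counts at 6 h, at 48 h and for 48 h against 6 h were 3525, 4176 and 3093. They moved to 1195, 2058 and 1894 with the third 48 h array added. In the 6 h comparison that array enters neither group mean, so the changes are the same and only the variance estimate differs. For the other comparisons the cause was not tested. With only the compared groups fitted, which has fewer residual degrees of freedom, the counts moved to 2086 at 48 h and 1759 for 48 h against 6 h. They moved to 1068, 1385 and 848 at adjusted p under 0.01, and to 1317, 1633 and 1040 with a log2 change of at least 1. Leaving out 1 array gave 0 to 3274, 1673 to 3353 and 0 to 2228, where the lone array of a group is assumed to vary like the others; beside the counts of 0, limma had 4413 genes at an unadjusted p under 0.05 at 6 h without 6 h replicate 1, and 4220 and 4520 for 48 h against 6 h without 6 h replicates 1 and 2. The fall in degrees of freedom accounts for part of this by construction, and the rest was not tested. With the replicate number as a block the counts were 2796, 3534 and 2284; the labels do not say that the numbers pair samples, and residuals of equal numbers correlated at only -0.014, 0.069 and 0.069 across genes. The alternatives added gave 3694, 4367 and 3215, then 4019, 4682 and 3559, then 4392, 5004 and 3932, and 3585, 4005 and 3015, in the order listed. The share rising was 59.5%, 62.2% and 51.9% with 75th percentile scaling and 47.1%, 50.4% and 52.8% with cyclic loess, against 51.7%, 48.0% and 44.2%. At adjusted p under 0.01 it was 45.4%, 38.6% and 51.1%. List calls went from 58 of 84 to 0 with an estimated correlation, and were 54 to 57 with 1 array left out. A null widened by that correlation cannot be the only reason for the 0. For microRNA proteins from 6 h to 48 h the estimate was 0.002, below the preset 0.01, yet camera p rose from 0.157 to 0.228. With 3 residual degrees of freedom, that version did not call even mitosis at 48 h, where 50 of 52 members rose. It therefore cannot separate lists that moved from lists that did not. Fry called lists that camera did not: stromal markers at 6 h (adjusted p = 0.0106) and from 6 h to 48 h (adjusted p = 0.00890), feedback regulators at 48 h (adjusted p = 0.0219) and microRNA proteins from 6 h to 48 h (adjusted p = 0.0183). The share of 48 h calls in the same direction on the third 48 h array, 87.1%, was 94.3% at adjusted p under 0.01, 93.9% at a log2 change of at least 1, and 85.1% to 87.3% with 1 resting array as baseline. Of 360 named gene and comparison pairs 344 passed, 0 reversed, and 34 passed in every planned setting tried on them but the stricter thresholds. The filter on unnamed probe sets was not tried on these pairs. Only pairs of 48 h against rest could be among the 34, since leaving out 6 h replicate 1 removed every call of the other comparisons. Signal over background limits genes near or below the background guide of 5.97, such as Il2 and Lif at rest and H2ac4 at 6 h, whose folds depend on the floor of the array. Simulated changes of 0.5 were recovered in 0% to 2% of genes, but only 200 of 43029 probe sets were changed there. In the data smaller changes also passed, such as Kansl3 at -0.25 at 48 h (limma adjusted p = 0.0356).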

Other observations

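All the tests of hypotheses in this part were chosen only after the result was seen, and its genes were chosen after their values were seen.

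The 48 h replicates differed by over 1 on the log2 scale in 188 genes, against 62 at 6 h and 242 at rest. Higher on 48 h replicate 1 were Tbx21, the transcription factor of Th1 cells, at 10.00 against 6.50, the granzyme gene Gzmb at 8.74 against 6.06, Ly6a at 12.12 against 8.91, Gbp2 at 11.81 against 9.70 and Iigp1 at 9.63 against 7.62, the last pair being interferon-inducible GTPase genes. Lower on it were Ms4a4b at 8.95 against 10.92 and Itga4 at 7.53 against 9.05. The third 48 h array had 12.34 for Ly6a and 12.07 for Gbp2, closer to replicate 1, and 9.80 for Itga4 and 12.29 for Ms4a4b, closer to replicate 2. At rest, 173 of the 242 genes were higher on resting 1, including Mpo, a myeloid granule enzyme gene, at 9.92 against 7.27, Lyz2 at 8.97 against 6.80 and Aldh1a1 at 8.47 against 6.26.

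On the third 48 h array the genes furthest above the other arrays were Itga7 at 9.52, Anxa2 at 10.63, Mgarp at 9.13 and Ankrd37 at 10.05, against 48 h means of 6.12, 7.55, 6.32 and 7.95. Ndrg1 was at 10.94 against 8.70 and Aldoc at 11.17 against 8.69.

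A hypothesis for the 48 h difference is a stronger interferon gamma response in replicate 1, which may also explain the Gbp2 and Iigp1 values. Of 17 interferon gamma induced genes above background whose values had not been seen when their list was made, 16 were higher on replicate 1, with a median of 0.45, past the 0.3 set for the test, while the median over all genes was 0.05. Against rest, these 17 genes had a median of -0.51 at 48 h, with 11 lower. The test compares the replicates only, so it cannot tell a stronger response in replicate 1 from a deeper fall in replicate 2. The gap between replicates is not particular to these genes: oxygen-regulated genes not seen before had a median of 0.30 (18 of 20 higher) and the fixed glycolysis list 0.38, while the fixed interferon-stimulated list had 0.08. The list shares 16 of its 31 measured genes with the fixed lists, 11 had been seen, and 25 were above background at 48 h, from whichever cells in the samples. Ifng itself had 5.86 on replicate 1 and 5.34 on replicate 2, both below the background guide of 5.97. That guide is a 95th percentile, and the receptor probe sets behind it had medians of 3.63 and 3.70 on these arrays. Ifng was thus not shown to be absent. The source of any interferon gamma is open, and a batch difference between the replicates was not tested.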
